A study of Gallus gallus with 6 samples.

How the data were processed

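The data came from 6 single-colour Affymetrix chicken arrays of total RNA from exponentially growing DT40 cells, a chicken B cell line, with 2 arrays for each of 3 groups. Per the labels, the groups were wild type cells, K11 cells, described as a knock out of endogenous H1, and K11-5 cells, described as complete H1 null. Per the labels' protocols, RNA was labelled with a one-cycle kit, and each culture was kept at 39.5 °C with 100 nM of the pan-caspase inhibitor Z-VAD-FMK because apoptosis is induced in H1 null cells. What separates K11 from K11-5 beyond these words is not given in the sources used here. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

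The deposited values were linear probe set intensities, 1 per probe set and array, for 38535 probe sets. Per the submitters' processing notes they were made with GCOS, whose version, signal algorithm and scaling target are not given in the sources used here. The 96 AFFX control probe sets were left out, which left 38439. Means trimmed by 2% at each end ran from 48.0 to 77.7 over the arrays, a ratio of 1.62 between the highest and the lowest. The rule set before the data were examined kept the deposited scale where these means agreed within 5%, so the values were quantile-normalized.

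Intensities were transformed as log2(value + 2), where 2 was the 20th percentile of the deposited values rounded to a whole number. Fold changes are on this scale and understate the change of dim probe sets. Probe sets with a mean at or above the 40th percentile, a signal of 5.82, were tested, which gave 23063. A model with a mean per group was fitted to the 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). It had 3 residual degrees of freedom and 6.96 prior degrees of freedom. The number of arrays limits the precision. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the probe sets tested in a comparison, and the threshold was 0.05. The 3 comparisons were K11-5 against wild type, K11 against wild type and K11-5 against K11, with a moderated F-test over the 3 groups.

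Of the 38439 probe sets, 27168 had 1 gene symbol in the platform annotation, 177 had several and 11094 had none. For 26853 of those with 1 symbol the gene was matched to RefSeq genes of assembly GRCg7b, used for current names, chromosomes and the order of neighbouring genes. No gene was named from a probe set with several symbols. The tested probe sets stood for 10014 genes. Background was taken as the 95th percentile of 23 AFFX control probe sets for bacterial and tag sequences, placed on the normalized scale, a signal of 11.3; this floor was chosen after the data were seen. Where the dimmer group's mean lay under it, the change is given as a lower bound, the brighter group's mean over this floor, both with the 2 of the log transform added.

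Named genes followed a rule set before the data were examined. They were the probe sets of linker histone genes, then in each comparison the 10 largest rises and the 10 largest falls among probe sets past the threshold that had 1 gene symbol other than a LOC or clone name, non-overlapping groups and a higher group at or above the median signal, then up to 4 tested members of smallest p from each list discussed. Other genes are named as chosen after their values were seen. Before the data were examined, 26 gene lists were fixed, covering linker histones, H5 and variant linker histones, replication-dependent and variant core histones, chromatin architectural proteins, chromatin modifying enzymes, apoptosis, p53 targets, B cell genes, T cell, erythroid, myeloid, fibroblast, neuronal and germline markers, replication, mitosis, DNA repair, unfolded protein stress, heat shock, cholesterol synthesis, glycolysis, interferon response, NF-kB and immediate early genes, ribosomal proteins and oxidative phosphorylation. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, that of highest mean, and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. For the 29 chromosomes with at least 50 tested genes, the median over genes in each array, relative to the array's median, was compared between groups with limma without a trend, with Benjamini-Hochberg adjustment over chromosomes; this test was chosen after the data were seen.

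The model fit, the list test and the chromosome test were tested on simulated data drawn from the fitted means and spreads. In the K11-5 against wild type comparison over 23063 probe sets, 17% of 100 probe sets changed by 1 on the log2 scale were recovered and 63% of 100 changed by 2, with 7 false calls. In a separate simulation of that comparison, 90.5% of 200 probe sets changed by 4 were recovered, with 12 false calls. Of 23 lists with no simulated change none passed, and a list shifted by 0.5 passed. A chromosome shift of 0.4 was recovered as 0.366, with 0 false calls over the other chromosomes. Each probe set was simulated independently of the others. In the data, the correlation that camera estimated within a list ran from -0.129 for core histone variants to 0.645 for cholesterol genes. The simulations therefore do not show how many false calls correlated genes would give in the list and chromosome tests. The alternatives were other pseudocounts, filters, normalizations and variance models, only the compared groups, the replicate number as a block, 1 probe set per gene and leaving out each array. After the data were seen, a fit with 1 wild type array for each line was added for the overlap between the lines. The values without normalization, scaling by the trimmed mean, a pseudocount 16 times larger and a fit without genes of the shifted chromosomes were added after the data were seen.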

Results

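Gene expression was measured in 6 arrays of chicken DT40 cells, 2 each of wild type, K11 and K11-5, to compare cells labelled as lacking histone H1 with wild type cells. Linker histone H1 binds the DNA that enters and leaves the nucleosome. Mean deposited signals trimmed at both ends were 77.7 and 66.7 in the wild type arrays, 56.0 and 48.0 in the K11 arrays and 59.5 and 68.4 in the K11-5 arrays. The ratio of 3' to 5' actin control signals, a measure of RNA and labelling quality, was 8.10 and 7.15 in wild type, 9.23 and 9.31 in K11 and 6.29 and 5.28 in K11-5. The same ratio for GAPDH was 0.892 and 0.917 in wild type, 0.832 and 0.819 in K11 and 0.914 and 0.798 in K11-5. Normalized log2 signals correlated across probe sets with r = 0.954 between the wild type arrays, 0.931 between the K11 arrays and 0.939 between the K11-5 arrays; probe sets are not independent replicates.

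Linker histone signals did not separate the groups as their labels do. HIST1H111L, the linker histone gene with a bright probe set, had normalized signals of 1623 and 2161 in wild type, 5791 and 1576 in K11 and 4776 and 4426 in K11-5. Its log2 fold change was 1.29 ± 0.44 (SE) in K11-5 against wild type, with limma's adjusted p = 0.134, and 0.69 ± 0.44 in K11 against wild type, with adjusted p = 0.417. HIST1H111R was dim, with signals of 9.2 and 1.2 in wild type, 32.7 and 21.1 in K11 and 34.4 and 16.8 in K11-5. H1FOO, an oocyte linker histone, lay at 1.9 to 13.1 in the 6 arrays and was not tested. Where these probe sets lie relative to any deleted part is not given in the sources used here, so they do not check the labels. A difference between the groups did appear at reporter probe sets, which carry sequences that are not chicken genes. Of 57 reporter probe sets, 6 were above the background of 11.3 in both arrays of K11 or K11-5 and below it in both wild type arrays. One of them, based on U57609, had deposited signals of 0.9 and 0.5 in wild type, 2231 and 1545 in K11 and 2758 and 2357 in K11-5. Another, based on AF062997, had 76.3 and 126.6 in K11, and 0.6 and 1.4 in K11-5, as in wild type.

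**Figure D1:**
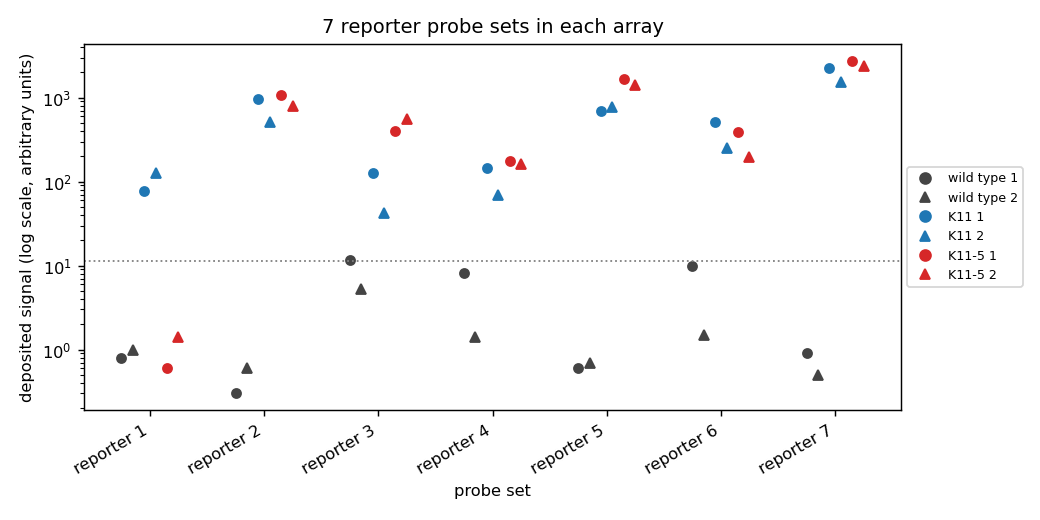
Deposited signals (log scale, arbitrary units) of 7 reporter probe sets, in the order AF062997, AF403737, AJ002682, K01193, L36849, NC_002086 and U57609, with 1 point per array and the background as a dotted line at 11.3. The first was high in the K11 arrays (76.3 and 126.6) and near 1 in the others, and the rest were high in K11 and K11-5.

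The comparison of K11-5 with wild type asked how gene expression differs in cells labelled complete H1 null. Of 44 tested genes in the B cell list, 10 fell and 1 rose in K11-5 (camera adjusted p = 8.13e-06; adjusted p = 0.774 with an estimated correlation). Of 9 tested core histone probe sets, 5 rose and 1 fell. VPREB3, a surrogate light chain protein of B cells, was at least 28.5-fold lower, CD72, a B cell coreceptor, at least 21.5-fold lower, and BTLA, an inhibitory receptor of lymphocytes, 91.6-fold lower, with signals of 16.4 and 9.3 in K11-5 against 954 and 1819. IRF4, a transcription factor of B cell differentiation, fell by 4.49 ± 0.93 (SE) on the log2 scale (adjusted p = 0.0234). HSPB9, a small heat shock protein, rose 26.9-fold, from 234 and 94.8 to 3687 and 4474 (adjusted p = 9.26e-05).

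The B cell list had a median log2 fold change of -0.91. Adjusted over the list alone, 21 fell and 2 rose. The number that fell was 3 without wild type replicate 2 and 17 without K11-5 replicate 1, and the median was -0.51 without K11-5 replicate 2. CD79B, a signalling chain of the B cell receptor, fell by 4.33 ± 0.65, and BTK, a kinase of that receptor, fell by 1.74 ± 0.22. BLB1, an MHC class II beta chain whose probe set can detect its close relatives, was at least 6.71-fold lower, and RASGRP3, an activator of Ras, at least 12.3-fold lower. IGLL1, the name the annotation gives to an immunoglobulin light chain gene, was the member that rose, by 1.23 ± 0.20. The fall was deeper in K11-5 replicate 2. Among the 10 members that fell, the median difference from the wild type mean was -2.30 in replicate 1 and -3.64 in replicate 2, and IRF4 was 261 in the first and 13.4 in the second. The K11-5 arrays also had the lowest ratios of 3' to 5' actin signal, 6.29 and 5.28. Markers of other cell types showed no shift past the threshold. In the T cell, erythroid, myeloid, fibroblast, neuronal and germline lists the median log2 fold changes were 0.05, -0.10, 0.34, 0.14, -0.04 and 0.46, with camera adjusted p from 0.578 to 0.893. Single markers did pass, among them CD3D, a T cell receptor component, which fell by 1.99 ± 0.26, and CEBPB, a myeloid transcription factor, which rose by 2.01 ± 0.36.

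**Figure D2:**
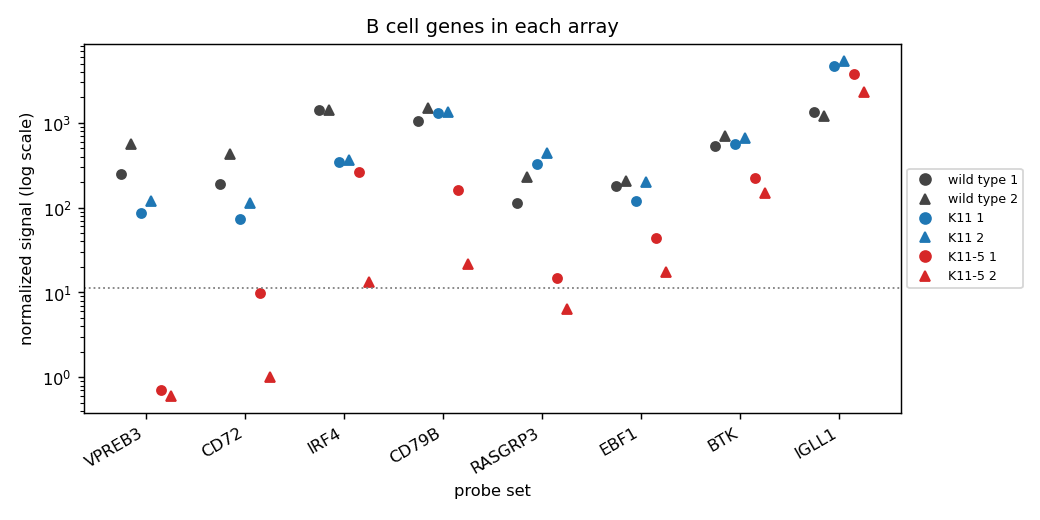
Normalized signals (log scale) of 8 B cell genes, 1 point per array, with the background of 11.3 as a dotted line. In K11-5, VPREB3 lay at 0.7 and 0.6 against 251 and 569 in wild type, while IGLL1 was higher in K11 and K11-5 than in wild type.

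Core histones package DNA, and most of their probe sets are assigned to several near-identical genes, so they are described by family; this grouping was chosen after the values were seen. The 9 tested had a median log2 fold change of 0.99 in K11-5 against wild type. The ratio of 3' to 5' actin signal was lowest in K11-5, 6.29 and 5.28 against 8.10 and 7.15 in wild type. An H4 probe set rose by 2.02 ± 0.16 (adjusted p = 0.000267), from 412 and 334 to 1452 and 1576. A probe set for H2B rose by 1.58 ± 0.16 (adjusted p = 0.000872). The one that fell was another H4 probe set, assigned to the same 5 genes as the H4 probe set that rose. Its signals were 6.6 and 4.0 in K11-5, below background, against 60.8 and 43.3. Why these H4 probe sets disagree was not tested. The rises for H2B and for H3 each came from a pair of probe sets with the same assigned genes, so the 5 rises are not separate results. The count that rose was 3 when either wild type array or either K11-5 array was left out, 3 on the deposited scale and 0 in limma without the intensity trend in the variance, where 7 of the 9 had an unadjusted p under 0.05. The fall did not pass without either wild type array or without K11-5 replicate 2. Of 6 core histone variants tested 0 passed limma's threshold, 3 had an unadjusted p under 0.05, and the list's camera adjusted p was 0.578.

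**Figure D3:**
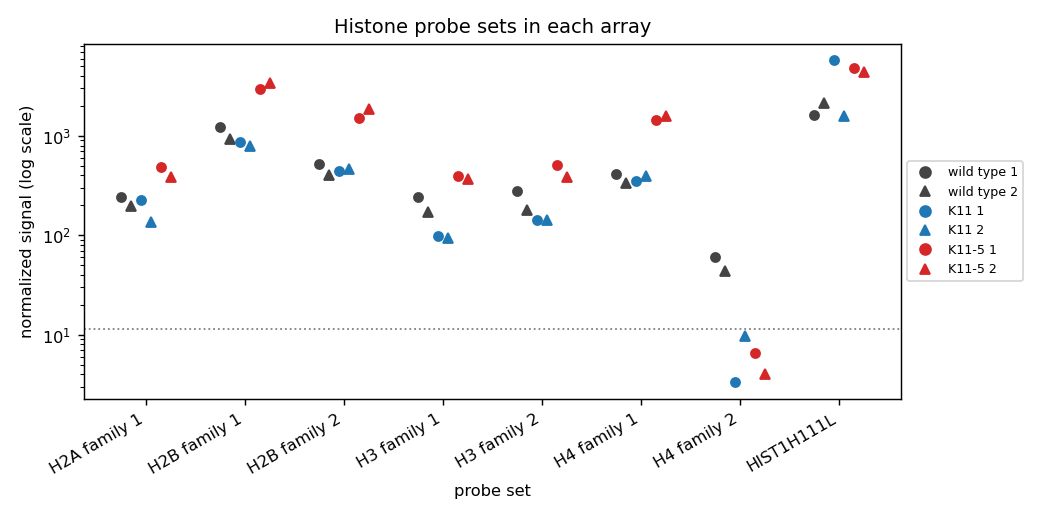
Normalized signals (log scale) of 7 core histone probe sets with several genes each, and of HIST1H111L, 1 point per array, with the background of 11.3 as a dotted line. The first H4 probe set lay at 1452 and 1576 in K11-5 against 334 to 412 in wild type and K11.

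Of 23 cholesterol synthesis genes 5 fell and none rose in K11-5, with a median of -0.64 (camera adjusted p = 0.000181; adjusted p = 0.774 with an estimated correlation). Adjusted over the list alone, 10 fell. The number past the threshold was 1 without either wild type array or without K11-5 replicate 2, 2 without K11-5 replicate 1, and 12 and 11 without K11 replicates 1 and 2. Without genes of the shifted chromosomes 1 of 14 fell, with a median of -0.39. Mevalonate kinase, MVK, fell by 1.45 ± 0.19, and SQLE, squalene epoxidase, fell by 1.28 ± 0.25. Of 42 apoptosis genes 2 rose and 4 fell, and the list had a median of -0.13 (camera adjusted p = 0.385). CASP8, an initiator caspase, rose by 1.65 ± 0.21, BCL2L1, an inhibitor of apoptosis, fell by 1.70 ± 0.34, PDCD4 fell by 1.08 ± 0.14, and BOK, a pro-apoptotic relative of BCL2, fell by 1.38 ± 0.31. The others past the threshold, named after their values were seen, were BMF, a pro-apoptotic protein, which rose by 1.41 ± 0.35, and CYCS, cytochrome c, which fell by 0.67 ± 0.16. Of the chromatin architectural proteins, HMGN2P46 and HMGB2 rose by 1.08 ± 0.17 and 0.91 ± 0.19, while RAD21 fell by 0.71 ± 0.13 and CBX3 fell by 0.72 ± 0.17. The list did not pass (camera adjusted p = 0.578). Of 39 chromatin modifying enzymes, SUV39H2, a histone H3 lysine 9 methyltransferase, fell by 0.76 ± 0.18, and 38 did not pass the threshold (list camera adjusted p = 0.823).

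Large single changes outside these lists included HINTW, a gene of the W chromosome, at least 364-fold lower, with signals of 4776 and 4917 in wild type against 0.7 and 1.8. The largest rises included AKR1B10, an aldo-keto reductase, at least 13.0-fold, and PPDPF, with 29.8 and 17.3 in wild type against 389 and 2573. LCP1, an actin-bundling protein, rose at least 7.68-fold. In all, 600 probe sets were higher and 660 lower among 23063 tested. On the deposited scale 305 were higher and 809 lower, with a median over all tested probe sets of -0.12. More probe sets were higher than lower without wild type replicate 1 (219 and 154) and without wild type replicate 2 (97 and 59). The total of 1260 fell to 27 without the intensity trend in the variance. It was 373 and 156 without wild type replicates 1 and 2, 714 and 318 without K11-5 replicates 1 and 2, and 1942 and 1932 without K11 replicates 1 and 2, and 16 of the 20 named rises and falls stayed past the threshold without K11-5 replicate 2 and 7 without the intensity trend.

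Wild type and K11 were compared to ask how cells labelled as a knock out of endogenous H1 differ from wild type, and the K11 arrays also differed from wild type in reporter signals and in shifts of whole chromosomes. Of 23 tested cholesterol synthesis genes 13 fell in K11 (camera adjusted p = 4.51e-10; adjusted p = 0.703 with an estimated correlation). HMGCS1, which makes HMG-CoA, fell by 1.71 ± 0.22, from 748 and 599.5 to 166 and 248 (adjusted p = 0.00249). INSIG1, a sterol sensor, had a log2 fold change of -1.91 ± 0.27. The list's median was -1.10. Adjusted over the list alone, 17 fell. The K11 arrays had the highest ratios of 3' to 5' actin signal, 9.23 and 9.31. The number past the threshold was 3 and 5 without wild type replicates 1 and 2, and without K11 replicate 1 it was 7, with a median of -0.60. GPM6A, a neuronal membrane glycoprotein, rose at least 10.4-fold, DCX, a microtubule protein of migrating neurons, at least 15.2-fold, and HSPA12A at least 10.3-fold. SLA, an adaptor of lymphocyte receptor signalling, rose from 55.1 and 59.3 to 982 and 862. MTHFS, an enzyme of folate metabolism, fell at least 24.8-fold.

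Heat shock, oxidative phosphorylation, NF-kB and myeloid lists also passed camera's threshold in K11. Of 27 heat shock proteins 4 fell, among them HSPA8, which fell by 0.84 ± 0.13, and its cochaperone DNAJA1, which fell by 1.93 ± 0.31, with a list median of -0.29 (camera adjusted p = 0.00209; adjusted p = 0.821 with an estimated correlation). Adjusted over the list alone, 13 fell and 1 rose. Without genes of the shifted chromosomes 0 of 20 heat shock proteins passed in limma, with 10 at an unadjusted p under 0.05. The list's median was then -0.29 (camera adjusted p = 0.0016). In limma 0 heat shock proteins passed without wild type replicate 1 or 2, with 13 and 11 at an unadjusted p under 0.05, 2 fell without K11 replicate 1, and 15 fell without K11 replicate 2, with a median of -0.50. On the deposited scale 19 fell, with a median of -0.76, where the median over all probe sets was -0.32, and with arrays centred on their medians the list had -0.47. Of 64 oxidative phosphorylation genes 8 fell, such as SDHA, which fell by 0.76 ± 0.13, with a median of -0.19 (camera adjusted p = 0.00209; adjusted p = 0.821 with an estimated correlation), and the list's adjusted p was 0.263 without K11 replicate 1. Without wild type replicate 1 or 2, 0 of these passed in limma, with 11 and 13 at an unadjusted p under 0.05, and without K11 replicate 2 the number was 22 and the median -0.33. On the deposited scale 39 fell, with a median of -0.67, and 12 fell with arrays centred on their medians, with a median of -0.38. Of 31 NF-kB and immediate early genes 4 rose, including NFKB1 by 1.26 ± 0.19 and SPRY2 by 2.31 ± 0.45, with a median of 0.50 (camera adjusted p = 0.00648; adjusted p = 0.597 with an estimated correlation). Without wild type replicate 1 the number that rose was 1, and without wild type replicate 2 it was 0 in limma, with 8 at an unadjusted p under 0.05. On the deposited scale the NF-kB median was 0.16, with 2 higher and 1 lower. Of 12 myeloid markers 3 rose, CEBPB by 2.46 ± 0.36 and TLR2A by 2.37 ± 0.37 among them (camera adjusted p = 0.00271; adjusted p = 0.597 with an estimated correlation), with a median of 0.94. This call was lost without a filter (adjusted p = 0.0571), and the median was 0.57 without wild type replicate 1 and 1.82 without wild type replicate 2, where 1 rose. Adjusted over the list alone, 9 NF-kB genes and 6 myeloid markers rose. Of 19 germline genes 0 passed limma's threshold and 4 had an unadjusted p under 0.05, while fry gave the list an adjusted p of 0.00661 for a rise on balance; camera's adjusted p was 0.0956.

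The B cell list did not pass the threshold in K11 (median 0.21, camera adjusted p = 0.182). Of its 44 genes 4 rose and none fell, with IGLL1 up by 1.99 ± 0.20 and CD74, the MHC class II invariant chain, by 2.21 ± 0.45. Adjusted over the list alone, 6 rose and 2 fell. Some genes that were low in K11-5 were already dimmer in K11 than in wild type. VPREB3 had 86.95 and 119.4 in K11 against 250.8 and 569.2, and BTLA had 233.8 and 379.4 against 954.1 and 1819. CD72 had 73.5 and 112.5 against 189.7 and 427.6. RASGRP3 was instead brighter in K11, with 327.3 and 438.2 against 113.3 and 230.8. Of 42 apoptosis genes 3 rose and 6 fell. BCL2 fell by 2.61 ± 0.52, BCL2L1 fell by 1.91 ± 0.34 and CYCS fell by 1.21 ± 0.16, while PDCD4 rose by 0.74 ± 0.14. The list did not pass (camera adjusted p = 0.632). Of 31 chromatin architectural proteins 4 rose and 1 fell, and the list did not pass (camera adjusted p = 0.0521). SMC4 and SMC3, ATPases of condensin and cohesin, rose by 1.05 ± 0.18 and 0.88 ± 0.19, SMC2 by 0.50 ± 0.12, and CTCF, named after its value was seen, by 0.85 ± 0.21, while CBX3 fell by 0.71 ± 0.17. SMC4 and SMC3 did not pass on the deposited scale, with 0.46 and 0.34, and SMC2 had -0.062 there. Of 39 chromatin modifying enzymes, EP300, a histone acetyltransferase, rose by 1.26 ± 0.22 and RBBP4 by 0.58 ± 0.14, and the list did not pass (camera adjusted p = 0.701). Neither enzyme passed on the deposited scale, with 0.83 and 0.020. Of the 9 core histone probe sets none rose and 2 fell, with a median of -0.55. In limma 0 fell without wild type replicate 1 or 2, with 3 and 4 at an unadjusted p under 0.05, and 1 fell without K11 replicate 1. The median was -0.34 without wild type replicate 1 and -0.29 without K11 replicate 2.

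HINTW was at least 364-fold lower in K11 as well, at 6.5 and 17.7. Genes were also shifted by chromosome. In GRCg7b, genes of chromosome 2 shifted by -0.38 on the log2 scale in K11 and -0.39 in K11-5 against wild type, and genes of chromosome 11 by 0.48 and 0.45 (adjusted p over 29 chromosomes = 0.00012, 0.000125, 2.24e-05 and 3.26e-05, limma on chromosome medians). Chromosome 27 shifted by 0.32 in K11-5 and 0.090 in K11. Taken over probe sets, its K11 shift ran from -0.0142 to 0.108 over the settings, so its direction in K11 was not fixed. Between the lines, K11-5 minus K11 was 0.23 for chromosome 27, -0.14 for chromosome 26 and -0.15 for chromosome 34 (adjusted p = 0.00316, 0.00316 and 0.0208). Chromosomes 2, 9, 10, 11, 22, 24, 25, 27 and Z, each past the threshold in both lines, were set apart as shifted. W was set apart with them, but it had too few genes for the test, and no shift of W as a whole was shown. Of its genes, named after their values were seen, LOC430910 had -3.88 in K11 and -3.95 in K11-5. A probe set of HNRNPKL had -0.17 and -0.02, and a probe set of UBE2R2L had -0.09 and 0.21. Probe sets of NEDD4L differed, with -1.05 and -1.35 at one and -0.12 and -0.09 at another. Chromosomes 1, 20, 23, 26 and 34 passed in 1 line each and were not set apart. Of the 20 named rises and falls, 9 in K11-5 and 7 in K11 against wild type lay on the chromosomes that were set apart. With genes of the shifted chromosomes and those without a chromosome left out, 478 probe sets passed the threshold in K11-5 and 699 in K11 against wild type. In total 864 probe sets were higher and 912 lower. On the deposited scale these were 316 and 2615, with a median over all probe sets of -0.32, and 721 and 1481 with arrays centred on their medians. They were 967 and 868 with trimmed mean scaling and 215 and 88 without wild type replicate 1, and 176 of 279 were higher without wild type replicate 2, so which direction held more calls was not fixed. The total of 1776 fell to 21 without the intensity trend, to 303 and 279 without wild type replicates 1 and 2 and to 1158 without K11 replicate 1, and 16 of the 20 named rises and falls stayed past the threshold without wild type replicate 1 and 5 without the intensity trend.

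**Figure D4:**
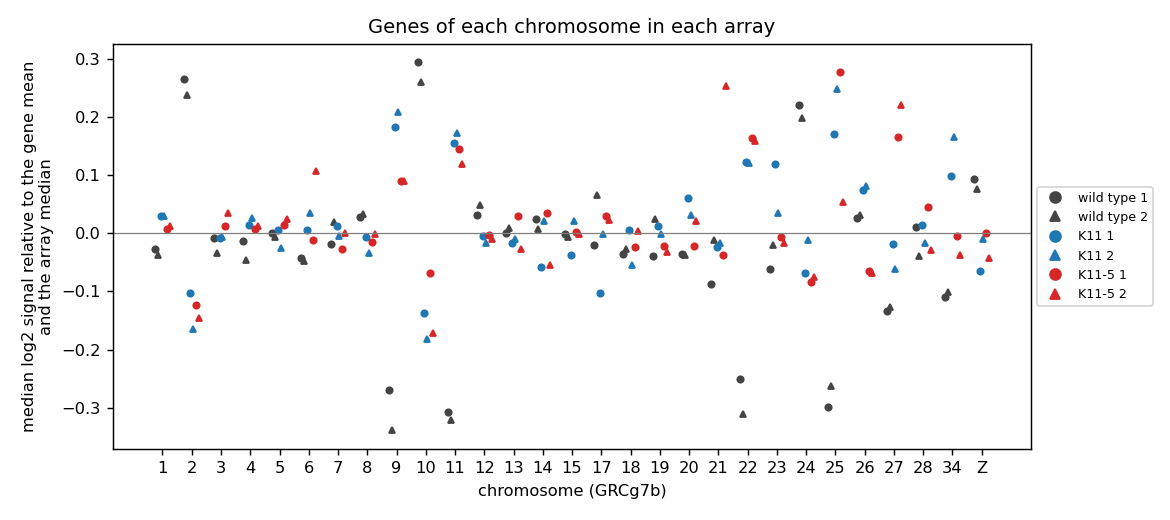
Median log2 signal of the genes of each chromosome in each array, relative to each gene's mean over the 6 arrays and to the array's median, for 29 chromosomes with at least 50 tested genes. On chromosome 2 the wild type arrays lay at 0.265 and 0.238 and the other arrays between -0.164 and -0.102.

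The direct comparison of K11-5 with K11 asked how cells labelled complete null differ from those labelled endogenous knock out. Of 44 B cell genes 14 fell and none rose in K11-5 (camera adjusted p = 2.31e-12; adjusted p = 0.674 with an estimated correlation). Of 27 heat shock proteins 5 rose and none fell (camera adjusted p = 2.54e-09; adjusted p = 0.674 with an estimated correlation). CD74 fell 16.6-fold, with 3202 and 2994 in K11 against 362.5 and 93.4 in K11-5 (adjusted p = 0.00374). At its other named probe set, the one used for the list and for K11 against wild type, CD74 fell 10.8-fold. CD79B fell 21.2-fold, RASGRP3 at least 28.6-fold and VPREB3 at least 7.79-fold. HVCN1, a proton channel of B cells, fell 15.3-fold. HSPB9 rose 26.3-fold, from 150 and 155.5 to 3687 and 4474, and HSPA2, a member of the HSP70 family, rose 10.1-fold.

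The B cell list had a median of -1.23, and 25 fell and 1 rose adjusted over the list alone. Without K11-5 replicate 2 the median was -0.61 and 5 fell. The heat shock list had a median of 0.53, and 14 rose and 1 fell adjusted over the list alone. The number that rose was 2 without either K11-5 array, 3 without wild type replicate 2 and 15 without K11 replicate 2, and the median was 0.32 without K11 replicate 1. On the deposited scale 16 rose, with a median of 0.91, where the median over all probe sets was 0.22. DNAJA1 rose by 1.77 ± 0.31 and HSPA8 by 0.74 ± 0.13. Of 9 core histone probe sets 6 rose and none fell, with a median of 1.88. Ratios of 3' to 5' actin signal were 6.29 and 5.28 in K11-5 and 9.23 and 9.31 in K11. Of 47 replication genes 4 fell, among them CCNE2, a cyclin of S phase entry, which fell by 1.65 ± 0.21, and SLBP, which binds the stem-loop of histone mRNA and fell by 0.97 ± 0.20 (list median -0.21, camera adjusted p = 0.00263; adjusted p = 0.730 with an estimated correlation). This call was lost without K11 replicate 2 (adjusted p = 0.278), with arrays centred on their medians (adjusted p = 0.106) and on the deposited scale (adjusted p = 0.311, median 0.073). Of the replication genes 2 fell without either wild type array, and without K11-5 replicate 2 it was 0 in limma, with 9 at an unadjusted p under 0.05.

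The cholesterol list was higher in K11-5 than in K11 (median 0.44, camera adjusted p = 0.00129; adjusted p = 0.730 with an estimated correlation) with 0 of 23 genes past limma's threshold, 9 at an unadjusted p under 0.05, and 7 higher and 1 lower adjusted over the list alone. Without K11 replicate 1 its adjusted p was 0.726 and its median 0.034. Without genes of the shifted chromosomes, which left 14 genes, they were 0.0523 and 0.40. The median was 0.81 without K11 replicate 2, where 10 rose, and 0.78 on the deposited scale, where 7 rose. Oxidative phosphorylation genes had a median of 0.11 (camera adjusted p = 0.0129; adjusted p = 0.730 with an estimated correlation), 1 of 64 fell and none rose, and the adjusted p was 0.970 without K11 replicate 1, 0.0894 without K11-5 replicate 1 and 0.0807 without the intensity trend. That median was 0.27 without K11 replicate 2, where 6 rose, and 0.18 without K11-5 replicate 2. It was 0.52 on the deposited scale, where 9 rose and none fell, 0.36 with arrays centred on their medians, where 2 rose and 1 fell, and 0.22 with trimmed mean scaling. The 1 fall did not pass without any of the 6 arrays but K11 replicate 1. Myeloid markers had a median of -0.41 (camera adjusted p = 0.0123; adjusted p = 0.674 with an estimated correlation), with TLR2A and NCF1C, a component of the phagocyte oxidase, lower by log2 fold changes of -2.55 ± 0.37 and -1.54 ± 0.27, and the adjusted p was 0.0998 without K11 replicate 2 and 0.0506 without a filter. The myeloid median was -0.86 without K11 replicate 1, where 1 fell, and -0.72 without K11-5 replicate 2, where 0 passed in limma and 3 had an unadjusted p under 0.05, and it was -0.18 on the deposited scale. Of 31 NF-kB and immediate early genes 1 rose and 3 fell, and that list did not pass (camera adjusted p = 0.112). JUN rose by 1.57 ± 0.28 and TRAF3 fell by 1.64 ± 0.29. Of 42 apoptosis genes 2 fell, PDCD4 by a log2 fold change of -1.82 ± 0.14 and BOK by -1.91 ± 0.31.

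In total 250 probe sets were higher and 405 lower in K11-5 than in K11. The split was 783 and 248 on the deposited scale, 529 and 370 with arrays centred on their medians and 556 and 500 without K11 replicate 2, and without K11 replicate 1 it was 220 and 223. Which direction held more calls thus depended on the scaling and on 1 array. The total of 655 in limma was 0 without the intensity trend, the 20 named rises and falls included, where 3323 had an unadjusted p under 0.05, and it was 306 and 287 without wild type replicates 1 and 2, 1056 without K11 replicate 2 and 96 without K11-5 replicate 2, where 11 of the 20 named rises and falls stayed past the threshold.

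Over the 3 groups together, 2318 probe sets passed the F-test; the number was 7 without the intensity trend, 633 and 432 without wild type replicates 1 and 2 and 1028 without K11-5 replicate 2. Changes against wild type overlapped between the lines. Of the probe sets that rose, 311 rose in both, among them LCP1, HSPA12A, SLC5A9 and SYPL1, where independent lists would share 22.5. Of those that fell, 288 fell in both, among them HINTW, MTHFS, FABP5 and BMERB1, where independent lists would share 26.1. The fold changes correlated across probe sets with r = 0.58, while 100 simulations of unchanged groups against the same wild type arrays gave 0.50. The covariance was 0.355 against a simulated 0.119, a difference of 0.236 that estimates the shared effect. With 1 wild type array for K11-5 and the other for K11, no control array was shared. Then r was 0.37 in 1 arrangement and 0.31 in the converse, with covariances of 0.260 and 0.231. In these, 46 and 62 probe sets rose in both lines, where independent lists would share 0.671 and 1.30, and 31 and 32 fell in both, where they would share 0.262 and 0.740. These overlaps were not tested for significance. Both wild type arrays may come from 1 culture, so a trait of that culture could still be shared. The comparisons also used the same estimate of the spread for each probe set, which can raise the overlap above that of independent lists. Of the 23 lists tested in each comparison, 21, 18 and 17 did not pass camera's threshold in K11-5 against wild type, K11 against wild type and K11-5 against K11, with adjusted p from 0.174 to 0.948, from 0.0521 to 0.880 and from 0.0752 to 0.894. In none of the 3 comparisons did a list pass with an estimated correlation, with lowest adjusted p of 0.774, 0.597 and 0.674. Median, mean and test differed in sign in lists that did not pass. In K11-5 against wild type these were the T cell, fibroblast, neuronal, mitosis and ribosomal protein lists. They were the unfolded protein stress and glycolysis lists in K11 against wild type, and the chromatin modifying, T cell, fibroblast and interferon lists in K11-5 against K11.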

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

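The test of array brightness given here was chosen after the result it concerns had been seen, and the test of S phase before. Signals appeared at reporter probe sets, which belong to no gene compared above. In the brighter of the K11 and K11-5 groups their mean deposited signals were 101.5 for AF062997, 936.6 for AF403737, 168.7 for K01193, 1546 for L36849, 380.9 for NC_002086 and 2557 for U57609, each below 11.3 in both wild type arrays. AF062997 was high in K11, and the other 5 were high in K11 and in K11-5. A probe set based on AJ002682 had 126.2 and 42.7 in K11 and 400.1 and 554.1 in K11-5, but 11.6 in a wild type array.

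Of 608 probe sets past the threshold in both lines against wild type, 9 went opposite ways. They were chosen for opposite changes past the threshold in both lines and for a difference past it in K11-5 against K11, so this difference is not separate evidence. Higher in K11 and lower in K11-5 than in wild type were CYB561A3 (K11-5 minus K11 on the log2 scale, -2.63), WDR66 (-3.89), UNG (-1.83), PDCD4 at its 2 probe sets (-1.92 and -1.82), TLR7 (-3.09), FAM107B (-3.69) and ARHGAP15 (-1.37). UNG removes uracil from DNA, and TLR7 is a receptor for single-stranded RNA. A core histone H3 probe set went the other way, with a difference of 1.97.

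Of 9 core histone probe sets 5 rose in K11-5 against wild type and 6 against K11. The K11-5 arrays were brighter than those of K11, which would raise probe sets of like signal as much, but on the deposited scale the 9 had a median of 2.02 against K11, while 0 of 1000 lists matched on signal were as high and the highest had 1.08. A larger share of cells in S phase would raise replication genes, with a median over 0.25. The 47 replication genes had a median log2 fold change of -0.148 against wild type, with an SD of 0.0775 over 1000 lists matched on signal. The median did not rise, but those lists drew genes singly, whereas the estimated correlation among the replication genes was 0.266. That SD is therefore too small for this list, and the test cannot decide on S phase. The test of brightness gives no verdict either. The rises were called after quantile normalization, which gives the arrays the same distribution of signals. Its matched lists also drew probe sets singly, whereas some of the 9 share genes. It shows only that on the deposited scale the median of the 9 against K11, 2.02, was above the 0.22 over all probe sets. A difference in histone mRNA processing or in how labelling captured these transcripts was not tested, and an effect of the state of H1 that the groups are named for stays open as a hypothesis. Probe sets shared by several genes leave open which genes changed.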

How the results depend on the processing

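The values without normalization, trimmed mean scaling, the pseudocount 16 times larger and the fit without shifted chromosomes were chosen after the data were seen. Of 13 lists past camera's threshold, 7 kept direction and side under 19 alternatives. Of 209 named gene results, 12 kept both under every one of these alternatives in which their probe set was tested. The higher filter and the fit without shifted chromosomes left some named probe sets out. Without the intensity trend the counts in K11-5 against wild type, K11 against wild type, K11-5 against K11 and the F-test were 27, 21, 0 and 7, where the 0 had 3323 at an unadjusted p under 0.05; the cause was not tested. With 1 probe set per gene, where 10014 were tested, they were 741, 1100, 403 and 1400. Without shifted chromosomes, where fewer genes were tested, the counts against wild type were 478 and 699 and the F-test gave 952. With only the compared groups in the fit, which leaves fewer arrays for the spread, the count was 2000 in K11-5 against wild type and 320 in K11-5 against K11. Without a filter the latter was 429, with 38439 tested. Without normalization the counts were 2931 in K11 against wild type and 1031 in K11-5 against K11, with medians over all probe sets of -0.32 and 0.22. Leaving out 1 array gave ranges of 156 to 1942, 279 to 2254, 96 to 1056 and 432 to 3098 for the 4 counts, and 0.49 to 0.66 for the correlation of fold changes; an arm left with 1 array was assumed to vary like the other groups.

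Reversals, by the direction of the test or the sign for single genes, were counted only where a result passed in the main setting or in the alternative. By this count 4 results reversed. The median of the replication list in K11-5 against K11 turned from -0.21 to 0.073 without normalization, where its call was lost and the test still pointed down. Without normalization the ribosomal protein list had a median of 0.16 in K11-5 against K11, and in K11 against wild type SMC2 had a log2 fold change of -0.062 and RFC4 -0.039. With trimmed mean scaling the ribosomal protein list had 0.17 in K11-5 against wild type. The cause was not tested. Without the intensity trend 0 members of the 13 called lists passed in limma, with 2 to 18 of a list at an unadjusted p under 0.05. With the pseudocount 16 times larger the B cell medians were -0.60 and -0.69 in K11-5 against wild type and K11, that of cholesterol genes -0.42 in K11-5 against wild type, and in K11 against wild type those of the NF-kB and myeloid lists 0.24 and 0.46. With the filter at the 60th percentile the myeloid medians were 1.63 in K11 against wild type and -1.27 in K11-5 against K11. With the replicate number as a replicate block the counts were 1235, 1703, 647 and 2184. Differences between replicates 1 and 2 correlated between groups, across probe sets, with r of 0.06, -0.04 and -0.03. No effect shared by arrays of the same number was thus seen, but the labels do not say whether they were paired. The planned quantile alternative was the same as the setting used and was not run, and robust variance was not run for lists. Probe sets under the background of 11.3 limit fold changes to lower bounds.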

Other observations

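The tests of signal intensity, of the reporters, of cells lacking the B cell genes and of copy number for the B cell genes were chosen after the results they concern had been seen. HSPA5, the main chaperone of the endoplasmic reticulum, fell by 1.29 ± 0.17 in K11-5 and fell by 1.82 ± 0.17 in K11 against wild type, and PDIA4, a disulfide isomerase, fell by 1.53 ± 0.18 and fell by 1.59 ± 0.18. Of 34 unfolded protein stress genes 5 fell and 3 rose in K11-5, and 9 fell and 4 rose in K11, and the list did not pass (camera adjusted p = 0.204 and 0.776). In DNA repair, 4 of 68 genes rose and 4 fell in K11-5 and 6 rose and 1 fell in K11 (camera adjusted p = 0.461 and 0.796). ATR, a checkpoint kinase, rose by 1.43 ± 0.21 in K11.

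Among p53 targets GADD45A rose by 1.45 ± 0.26 in K11-5, and 2 of 20 rose and 1 fell (camera adjusted p = 0.457). Of 34 glycolysis and hypoxia genes 2 rose and 3 fell in K11-5 (camera adjusted p = 0.376), and of 26 interferon response genes 2 rose and 2 fell (camera adjusted p = 0.893). Of 46 mitosis genes 0 passed limma's threshold in K11-5 against wild type and 11 had an unadjusted p under 0.05 (camera adjusted p = 0.676). Of 65 ribosomal proteins 0 passed and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.948). The replication-dependent core histone list had 1 tested gene, HIST1H2B5L, with a log2 fold change of 0.91 ± 0.73 in K11-5 (adjusted p = 0.565), and the list of H5 and variant linker histones had 0 tested.

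Genes of several chromosomes shifted together in K11 and K11-5 against wild type. An intensity bias would move genes of like signal elsewhere, but 0 of 1000 lists matched on signal had a median as low as that of chromosome 2 in K11, -0.37, and their lowest was -0.06. These lists drew genes singly and only from chromosomes that had not been set apart as shifted. Medians near 0 were therefore largely set beforehand, and the lists cannot decide on an intensity bias. A difference in chromosome copy number predicts a shift along the whole chromosome. In K11 against wild type, 40 of 40 groups of neighbouring genes on chromosomes 2, 9, 10 and 11 lay on their chromosome's side. A candidate explanation for these 4 in K11 is therefore a copy number that differs from these wild type cells, and DNA was not measured. In K11-5 these chromosomes shifted by -0.39, 0.39, -0.40 and 0.45, to the same sides, but groups of neighbouring genes were not examined there. Copy number is thus a candidate in K11-5 without that test. Chromosome 27, with 0.32 in K11-5 and 0.090 in K11, differed between the lines and was not part of this test. Of called probe sets with a chromosome, 45.9% in K11-5 and 45.2% in K11 lay on chromosomes 2, 9, 10, 11, 22, 24, 25, 27, W and Z, against 26.3% of those tested.

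Of 44 B cell genes 10 fell in K11-5 against wild type. Copy number of whole chromosomes would act through chromosome medians, and 0.996 of the median fall of the 10 members, -3.24, was left after these were subtracted. These members were chosen as past the threshold and lower, while genes of chromosome 10, for example, shifted by -0.40 in K11-5. Nearly all of so large a fall had to remain, so the subtraction is not a separate test. It shows only that whole-chromosome shifts were small beside these falls. Cells lacking the reporters as most of the culture would lower all of these, but of 6 reporters high in K11 and below the background in wild type, 5 had an interval of K11-5 minus K11 wholly above -2.72, the median change of 11 bright B cell markers against wild type, and the lowest of the 5 was -0.74; AF062997 was at least 8.75-fold lower, below the background, and earlier bounds were replaced after the values were seen. Cells of another type that lack the B cell genes, as the whole cause, would leave at most the 3.0% of wild type cells that VPREB3 allows. But 5 of the 10 other markers, a list written after several of its values had been seen, had intervals wholly above the level this leaves. With the 3.98% that CD72 allows 4 did, and IGLL1, outside that list, rose by 1.23 ± 0.20. Both shares take the remaining cells to have wild type levels of these genes. In K11, VPREB3 had 86.95 and 119.4 and CD72 had 73.5 and 112.5. Remaining cells like those of K11 could therefore make up a larger share, and this was not tested. Cells of another type that express part of these genes may remain: the bound set beforehand, an interval wholly above -1, was met by 0 of the 11 and decided nothing, and the changes ran from at least 28.5-fold lower for VPREB3 to a log2 fold change of -0.68 for IKZF3. That explanation and a change of state within the cells, with or without a role of H1, cannot be told apart with 2 arrays.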
